A study of Glycine max with 12 samples.

How the data were processed

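Gene expression was measured by RNA sequencing of soybean roots in 12 libraries, 3 for each combination of material (W or OX3) and MnSO4 concentration (5 or 50 µM). RNA was extracted with Trizol and libraries were made with a VAHTS Universal V6 kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say whether libraries of a group came from separately grown plants, so p-values measure only the spread between these libraries, which may be technical.

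The authors deposited a table of read counts per gene and a table of FPKM. The submitters' processing notes name CASAVA, Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0, without saying what each was used for. Whether counting used strand, and how reads shared by near-identical gene copies were assigned, is not given in the sources used here. Reads of similar or overlapping genes can therefore be divided in ways that cannot be seen in the counts. The count table held 43517 genes, of which 3303 had 0 counts in every library, and the other 40214 made up the FPKM table. Each deposited FPKM value equalled the count scaled by gene length and by the column total. The gene lengths recovered this way were whole numbers, with a largest deviation of 3.6e-12 and a median of 1884 bp, and 33.5% of them were multiples of 3. Identifiers carry the name of the Williams 82 annotation, Wm82.a2.v1. None of the identifiers matched the reference table of 59048 gene names (0 matched), so genes are given by identifier. For the same reason the 27 gene lists fixed in advance by product description had no member, and the planned list tests, markers of other root cell types included, could not be run.

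Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups, which left 31841, and libraries were scaled by TMM, with factors from 0.859 to 1.25. All 12 libraries entered 1 quasi-likelihood model with a coefficient per group, so that the groups share an estimate of the spread. F tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparisons were 50 against 5 µM in each material, OX3 against W at each concentration, and the interaction. Averages over materials and over treatments were added after the data were seen. Principal components and correlations used log2 CPM with a prior count of 2.

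Before the data were examined, the named genes were fixed as those with the largest fold changes past the threshold, at a mean of at least 2 CPM and with the groups compared not overlapping. Because no identifier could be paired with a name, at most 2 genes in each direction are given per comparison, or all where 5 or fewer passed. A group at 0 counts was given a floor of 3 counts over the group, which with the 95% intervals covers counting error only. In a single library 3 counts correspond to between 0.155 and 0.198 CPM of its raw total. The floor over a group is lower, since its 3 counts are set against the summed totals of the group.

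The procedure was tested on simulated counts with 50 genes changed at each fold. For Mn in W, with 31261 genes, it recovered 0% of 2-fold, 50% of 4-fold and 80% of 8-fold changes. For OX3 against W at control, with 31224 genes, these were 4%, 46% and 76%. For the Mn comparison over both materials, with 31269 genes, they were 18%, 78% and 96%, and for the interaction, with 31328 genes, 0%, 14% and 52%. In that order of comparisons, 5, 3, 16 and 2 unchanged genes were called. Counts were drawn independently for each gene and library, around 1 mean per gene. Structure shared between the real libraries was not simulated, so these rates may not hold for them.

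Replicate numbers are shared between groups without a stated meaning. Pairing was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. Between OX3 and W at control these correlations were 0.26, 0.45 and 0.27 for replicates 2, 3 and 4, and each library correlated best with its own number. The control libraries of OX3 and W were taken as possible pairs by number, on the evidence of the data and not of the labels. The value with the replicate block stands beside the comparison of OX3 and W at control.

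Alternatives were DESeq2 1.42.0, other size factors, other filters on low counts, limma 3.58.1 (voom, with and without sample weights, and limma-trend on log2 FPKM with a pseudocount of 1 or 0.1), a fit of the 2 groups alone, a replicate block, a fold-change minimum, and leaving out each library. A correction for gene length and a replicate block within treatment were added after the data were seen. The agreement of 2 sets of fold changes was tested by relabelling libraries, where 200 relabellings allow a smallest p of 0.005. Positions of genes along chromosomes were compared with 10000 shuffles. Python calculations used pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.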

Results

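RNA from soybean roots was sequenced in 12 libraries. Roots of 2 plant materials, labelled W and OX3, had received 5 µM MnSO4 as the control or 50 µM MnSO4 as the manganese (Mn) treatment. Each of the 4 groups held 3 libraries. The authors' tables head the W libraries WT and the OX3 libraries OX. Neither the labels nor the tables say what these stand for or name a gene, so no targeted gene could be checked. Total counts per library ranged from 15175866 to 19408318, and between 34494 and 36862 genes had at least 1 count. The 20 most abundant genes took between 5.74% and 10% of the counts of a library. Genes are given by their identifiers, such as Glyma.16G214500.Wm82.a2.v1, with the ending .Wm82.a2.v1 left off from here on. The number before the letter G is the chromosome, and the number after it gives the order of genes along that chromosome. Levels are CPM, the read count of a gene relative to the TMM-normalised total of its library, as mean ± SD with n = 3 libraries per group.

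Libraries of one group correlated across genes, which are not independent replicates, with r between 0.91 and 0.954. The first principal component held 33.7% of the variance and the second 18.9%. On the first component the W libraries at 50 µM lay between 55.8 and 108.9. The OX3 controls lay between -107.1 and -53. W control replicate 2 lay at -107.2, beside OX3 control replicate 2, whereas W control replicates 3 and 4 lay at -1.2 and 35.3. Its correlation with OX3 control replicates 2 and 3 was 0.958 for each, against 0.911 and 0.91 with the other W controls. On 20 genes separating the materials, chosen without it, its position was 0.25, nearer the W mean at 0 than the OX3 mean at 1. The other W libraries, placed in the same way, lay between -0.13 and 0.11. On the first component, OX3 replicate 4 at 50 µM lay at -16.8, apart from OX3 replicates 2 and 3 of that treatment at 60.7 and 35.6.

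**Figure D1:**
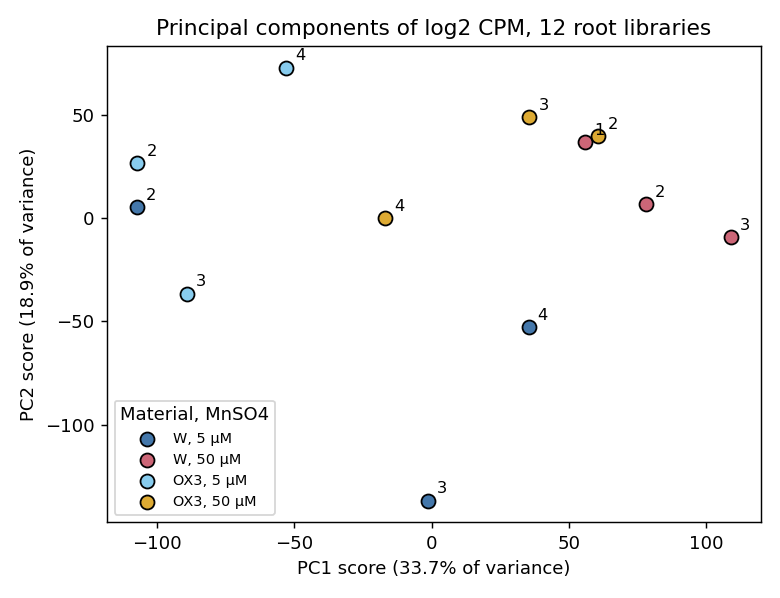
Scores of the 12 libraries on the first (33.7% of variance) and second (18.9%) principal components of log2 CPM, with each point a library, colours for the 4 groups and numbers for replicates. W control replicate 2 lies at -107.2 on the first component, beside OX3 control replicate 2 at -107.1.

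The first comparison asked which genes differed between 50 and 5 µM MnSO4 in W. Glyma.12G172300 rose from 4.38 ± 0.39 CPM (SD, n = 3) at 5 µM to 18.6 ± 1.2 CPM (SD, n = 3) at 50 µM. This was a log2 fold change of 2.09 (SE 0.19), with an adjusted p of 0.0068 in edgeR's quasi-likelihood test. It was the 1 gene past the threshold among 31841 tested. At an unadjusted p under 0.05 there were 5931 genes, 2696 higher and 3235 lower, where 1592 were expected by chance. That expectation, here and below, holds only if the libraries carry no structure other than the groups. Genes under that p were not counted in other splits of the libraries. DESeq2 called 1505 genes. The call on Glyma.12G172300 ended in a fit of the 2 groups alone (adjusted p 0.068 in edgeR) and with the replicate number as a block (0.18). That block leaves W replicate 1 at 50 µM out of the comparison, so its value does not show the effect of pairing alone. Without any one of 5 of the 6 libraries compared the count was 0 and the adjusted p of Glyma.12G172300 lay between 0.057 and 0.075, while without W replicate 3 at 50 µM the call remained.

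In OX3, the same treatment gave 0 genes past the threshold in edgeR's test, with 4774 genes at an unadjusted p under 0.05 against 1592 expected. DESeq2 called 1071 and limma-voom 0. The smallest adjusted p, 0.095 in edgeR, belonged to Glyma.06G302300, chosen after its value was seen. Its level was 23.4 ± 7.5 CPM (SD, n = 3) at 5 µM and 3.58 ± 0.37 CPM (SD, n = 3) at 50 µM, a log2 fold change of -2.71 (SE 0.32). Without OX3 replicate 4 at 50 µM the count was 8, and without OX3 control replicate 4 it was 2.

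Whether the response to Mn differed between OX3 and W was tested as an interaction. Glyma.12G172300 was the 1 gene past the threshold. Its level in OX3 was 8.62 ± 0.59 CPM (SD, n = 3) at 5 µM and 6.43 ± 0.9 CPM (SD, n = 3) at 50 µM, against the rise seen in W. The response in OX3 minus that in W was -2.51 on the log2 scale (SE 0.27), with an adjusted p of 0.029 in edgeR's test. Within OX3 alone the log2 fold change of -0.42 (SE 0.19) had an adjusted p of 0.32 in edgeR's test. The call on the interaction ended without any one of the 12 libraries, where edgeR's adjusted p lay between 0.075 and 0.21 and the log2 difference between -2.62 and -2.42. It also ended with the replicate number as a block (adjusted p 0.55 in edgeR, log2 difference -2.47), with the number within treatment as a block (0.37 and -2.41), without a filter on low counts, on log2 FPKM and with the length trend removed, while DESeq2 called 68 genes, this one included.

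Over both materials together, a comparison added after the data were seen, 740 genes differed between 50 and 5 µM in edgeR's test, 405 higher and 335 lower at 50 µM. Glyma.11G091600 rose from 1.59 ± 1.9 to 17.3 ± 6.9 CPM (SD, n = 3) in W and from 0.366 ± 0.48 to 15.5 ± 6.1 CPM (SD, n = 3) in OX3. Its log2 fold change over both was 4.44 (SE 0.68), and it was 5.31 without W control replicate 4 and 5.40 without OX3 control replicate 4. Glyma.09G269400 rose from 2.56 ± 3.8 to 19.7 ± 8.3 CPM (SD, n = 3) in W and from 0.477 ± 0.44 to 15.5 ± 5.2 CPM (SD, n = 3) in OX3. Glyma.12G059200 fell from 13.2 ± 9 to 1.14 ± 0.88 CPM (SD, n = 3) in W and from 6.79 ± 4.5 to 0.66 ± 0.93 CPM (SD, n = 3) in OX3. Glyma.03G092800 fell from 14.1 ± 7.2 to 2.67 ± 1.8 CPM (SD, n = 3) in W and from 19.8 ± 1.8 to 4.22 ± 2.2 CPM (SD, n = 3) in OX3. The adjusted p of each of these 4 genes over both materials was 0.044 in edgeR's test. By the rule that chose them, which 244 of the 740 met, all 6 libraries at 50 µM lay on one side of all 6 at 5 µM. That rule also asked for a mean of at least 2 CPM. The log2 fold change of Glyma.09G269400 was 4, and 5.38 without W control replicate 4, and that of Glyma.12G059200 was -3.41, and -4.60 without OX3 replicate 4 at 50 µM. The count of 740 lay close to the threshold. It was between 0 and 3 without any one of 9 libraries, but 1842 without W control replicate 4, 1721 without OX3 control replicate 4 and 1806 without OX3 replicate 4 at 50 µM. DESeq2 called 4042 genes, limma-voom 276, limma-voom with sample weights 2, and edgeR with the replicate number as a block 0.

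The fold changes to Mn in W and in OX3 share no library. Across the 31841 genes their correlation was r = 0.50, with a covariance of 0.292. They need not be independent, since deviations of same-numbered W and OX3 controls were correlated (0.26, 0.45 and 0.27). Any effect shared by the controls would enter both fold changes. The relabellings took no account of replicate numbers, so the permutation p-values do not allow for this. In an exact one-sided test over 200 relabellings of the libraries within each material, 10 gave a correlation as high, the real labelling included (p = 0.05), and the highest other was 0.70. Among genes at an unadjusted p under 0.05 in both materials, 751 were higher in both, against 195 expected for independent lists, and 618 were lower in both, against 252 expected. A further 85 went opposite ways. The expected numbers treat genes as independent, which they are not. Without W control replicate 2 the correlation was 0.27 (exact permutation p = 0.14), the lowest of 12 such fits. The highest, 0.59, came without W control replicate 4 (exact permutation p = 0.02) or without OX3 control replicate 4 (exact permutation p = 0.03).

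Between OX3 and W at 5 µM MnSO4, 4 genes differed in edgeR's test, 3 of them on chromosome 16. Glyma.16G214500 was at 4.72 ± 1.4 CPM (SD, n = 3) in OX3 and 0.252 ± 0.11 CPM (SD, n = 3) in W, a log2 fold change of 4.19 (SE 0.51) with an adjusted p of 0.028 in edgeR's test. Glyma.16G161000 was at 0.16 ± 0.18 CPM (SD, n = 3) in OX3 and 10.5 ± 0.85 CPM (SD, n = 3) in W. Glyma.16G171900 was at 43 ± 5.9 CPM (SD, n = 3) in OX3 and 136 ± 5.9 CPM (SD, n = 3) in W. Glyma.09G125600 had 0 counts in the OX3 controls and 120 in the W controls, at least 49.9-fold lower in OX3 when 3 counts over the group are taken as the floor. The adjusted p of each of these lower genes was 0.026 in edgeR's test. In all, 3259 genes had an unadjusted p under 0.05, against 1592 expected. With the replicate number as a block the count was 0 and edgeR's adjusted p of the 4 genes was 0.25. It was 100 without W control replicate 2, and 0 without any one of the other 5 libraries. Limma-voom and a fit of the 2 groups alone also gave 0, and DESeq2 217.

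At 50 µM MnSO4, 5 genes differed between OX3 and W. Glyma.16G214500 was at 10.6 ± 5.9 CPM (SD, n = 3) in OX3 and 0.181 ± 0.057 CPM (SD, n = 3) in W. Glyma.16G161000 had 3 counts in OX3 and 279 in W, and the 95% counting interval of the normalised ratio of W to OX3 ran from 34.3 to 495. Glyma.11G192400 was at 15.8 ± 2.9 CPM (SD, n = 3) in OX3 and 2.4 ± 0.27 CPM (SD, n = 3) in W, and Glyma.07G051200 at 25.9 ± 7.2 and 6.63 ± 1.5 CPM (SD, n = 3). Glyma.12G172300 was lower in OX3, with a log2 fold change of -1.54 (SE 0.19). This last comparison uses the same W libraries at 50 µM as the treatment comparison above. Adjusted p-values of the 5 genes ranged from 0.008 to 0.044 in edgeR's test. There were 2789 genes at an unadjusted p under 0.05 against 1592 expected. The count was 0 without W replicate 1 or 2 at 50 µM, 3 without W replicate 3, of which 1 was among the 5, and 1 without any one of the OX3 libraries. It was also 0 in limma-voom, in a fit of the 2 groups alone and with the replicate number as a block, while limma-voom with sample weights gave 23 and DESeq2 231, each with all 5.

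**Figure D2:**
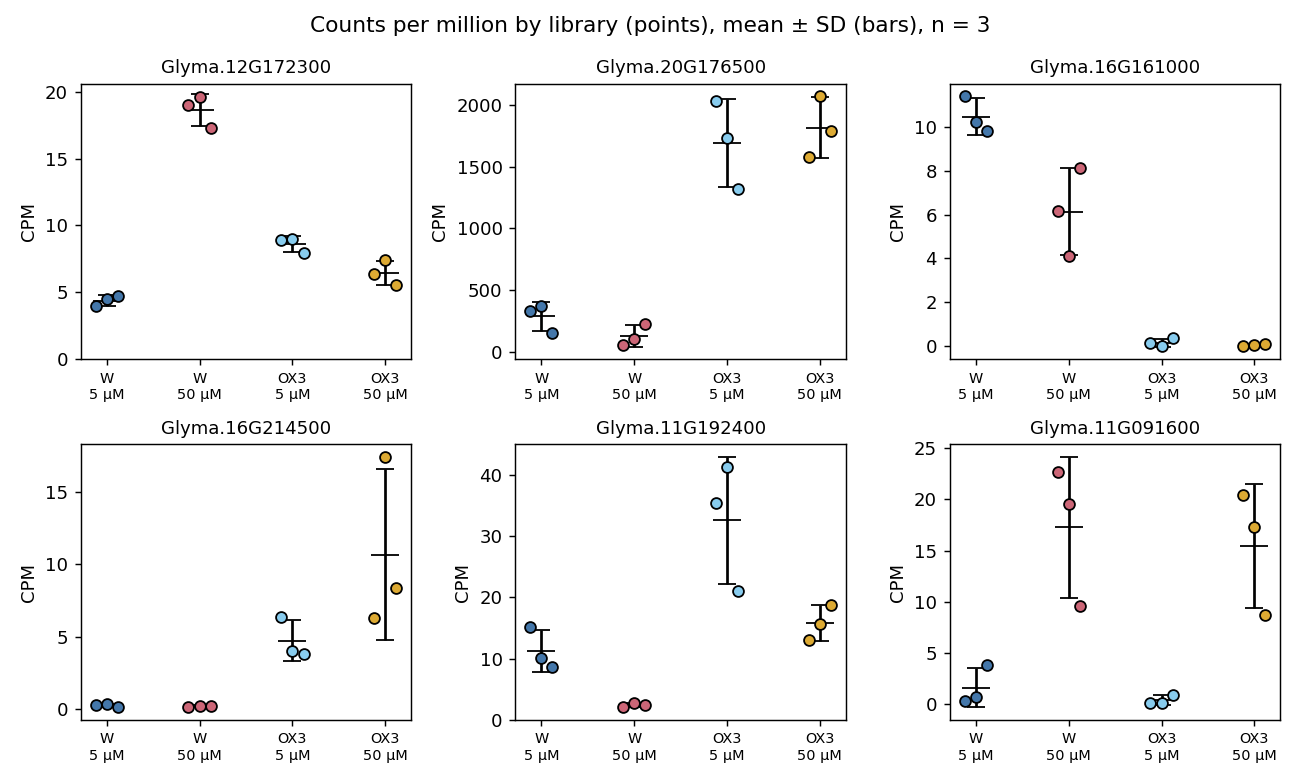
CPM of 6 genes in each library (points), with the mean ± SD of each group (horizontal mark and bars, n = 3), on linear axes that differ between genes. Glyma.12G172300 rose in W from a mean of 4.38 to 18.6 CPM and not in OX3, Glyma.16G161000 was near 0 in OX3, and Glyma.20G176500 was at 1320 CPM or more in each OX3 library.

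Averaged over both treatments, a comparison also added after the data were seen, 47 genes differed between OX3 and W in edgeR's test, 28 higher and 19 lower in OX3. Glyma.16G214500 had a log2 fold change of 5.02 (SE 0.37) and an adjusted p of 0.00066. In W it had only 13 counts over the group at 5 µM and 8 at 50 µM, so the size of its fold change rests on few counts. Glyma.20G176500 was at 1700 ± 360 and 1820 ± 250 CPM (SD, n = 3) in OX3 at 5 and 50 µM, and at 286 ± 120 and 127 ± 85 CPM (SD, n = 3) in W. Its log2 fold change was 3.20 (SE 0.39), with an adjusted p of 0.0086 in edgeR's test. Glyma.16G161000 was lower in OX3 by a log2 fold change of -6.25 (SE 0.53), which was -6.84 without OX3 control replicate 4. Its neighbour in the numbering, Glyma.16G161100, had 0 counts in OX3 and 208 in W at 50 µM, at least 75.6-fold lower with a floor of 3 counts over the group. At 5 µM Glyma.16G161100 had 7 counts in OX3 and 319 in W, or 0.106 ± 0.092 and 5.95 ± 1.3 CPM (SD, n = 3). By the rule that chose these 4 genes, which 30 of the 47 met, all 6 OX3 libraries lay on one side of all 6 W libraries. The count was 579 without W control replicate 2 and between 20 and 43 without any one of the other 11 libraries, while DESeq2 called 590 and limma-voom with sample weights 153. With the replicate number as a block, 11 genes passed, all among the 47. With the number within treatment as a block, chosen after the data were seen, 123 passed, of which 32 were among the 47.

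Of these 47 genes, 18 lay on chromosome 16, which is 1.55% of its 1159 tested genes against 0.0945% of tested genes elsewhere (two-sided Fisher's exact test, p = 1.86e-14, and 3.9e-13 after Benjamini-Hochberg adjustment over 20 chromosomes and the unplaced genes). From Glyma.16G159300 to Glyma.16G214500, 17 of 233 tested genes differed, 6 higher and 11 lower in OX3. The boundaries of that stretch were set from these genes. Without W control replicate 2, where 579 genes passed, 39 of them lay on chromosome 16 (6.74%, against 38.3% with that library; Fisher's exact p = 0.000276). The 740 genes that differed between Mn doses showed no such concentration, the smallest adjusted Fisher's exact p over chromosomes being 0.458.

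**Figure D3:**
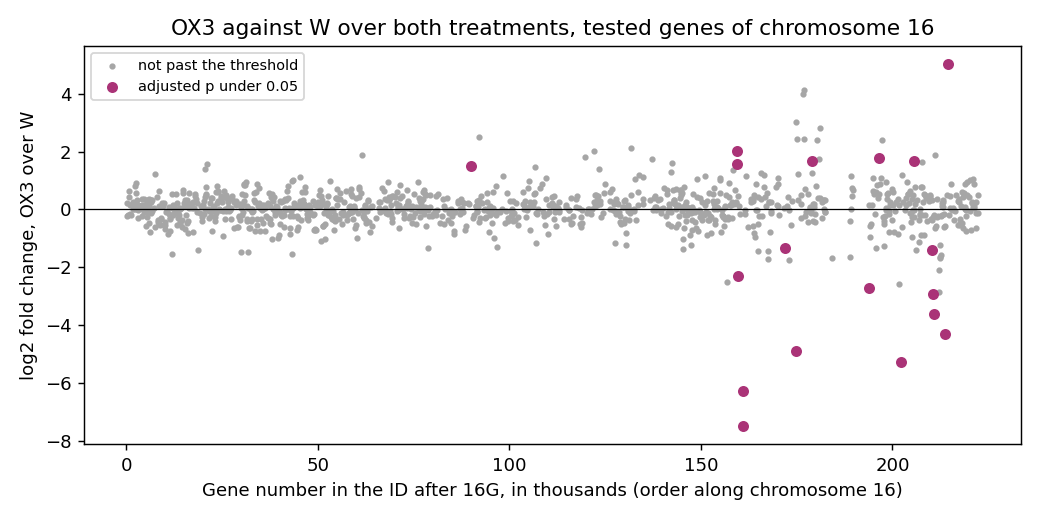
Log2 fold change of OX3 over W, averaged over both treatments, for the 1159 tested genes of chromosome 16, in the order of their identifiers (horizontal axis). The 18 genes past an adjusted p of 0.05 are the large points, 17 of them between Glyma.16G159300 and Glyma.16G214500.

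**Figure D4:**
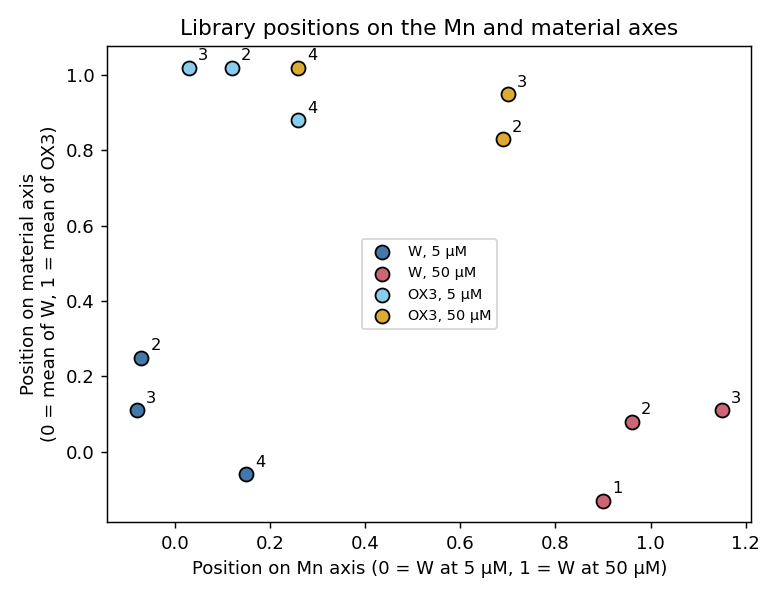
Position of each library on 2 axes. The horizontal axis uses the 200 genes with the smallest unadjusted p for Mn in W, of which 1 passed the threshold. On it, 0 is the mean of W at 5 µM and 1 that at 50 µM. The W libraries served to choose these genes, which favours their separation on this axis. The vertical axis uses 20 genes separating the materials (0 for W and 1 for OX3), chosen without the library plotted. OX3 replicates 2 and 3 at 50 µM lie at 0.69 and 0.70 on the Mn axis and OX3 replicate 4 at 0.26, where OX3 control replicate 4 also lies.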

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

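The comparisons over both materials or both treatments, the shuffles of gene positions, the window of Mn genes, the count of on/off genes among called genes, the window set from the control libraries and the splits that part the control pairs were tests chosen only after the result was seen. One result was marked because the effect of Mn differed between materials. For Glyma.12G172300 the log2 response in OX3 minus that in W was -2.51, the 1 gene past the threshold for the interaction. Of 40 splits of the 12 libraries, 3 gave as many genes, the real one included, so chance is not excluded for that count. Those 40 were the real split and others drawn at random from the possible ones, with material labels exchanged only within a treatment. The highest other split gave 303 genes, which points to a structure of the samples other than the labelled groups.

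The genes that differed between OX3 and W lay together on chromosome 16. Random placement is argued against, since the fullest window of 200 tested genes held 12 of the 47 and the highest of 10000 shuffles held 6 (permutation p = 0.0001, the smallest they can give). Neighbouring genes did move together in the Mn comparison too, with 29 adjacent pairs against a mean of 8.69 in shuffles, but the 47 genes with the smallest p for Mn put at most 3 in such a window, so that tendency as the whole source of the concentration is argued against. Differences in growth or handling within one treatment are argued against by 9 genes in a window of chromosome 16 set from the 6 control libraries alone, whose median log2 fold change in the 50 µM libraries, signed by direction at control, was 2.54; it was 2.17 for the other 41 genes picked in the same way, so this is not particular to chromosome 16, and the value of 2.73 for 13 genes of the stretch itself is favoured by its bounds, which the 50 µM libraries helped to set. A linked stretch of the genome that differs between the materials may be the source and stays open: genes near 0 in every library of one material and present in every library of the other made up 4 of 233 genes in the stretch and 2 elsewhere (Fisher's exact p = 4.23e-08), but the stretch was set from called genes, which favours that outcome, and a later test among called genes alone found 4 of 17 against 2 of 30 (Fisher's exact p = 0.17). Sequence differences from the reference and reads shared with similar genes were not tested, and what distinguishes the materials, headed WT and OX in the authors' tables, is not stated.

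OX3 replicate 4 at 50 µM lay near the OX3 controls. On 200 genes chosen in W its position was 0.26, within the range of the OX3 controls (0.03 to 0.26), and OX3 replicates 2 and 3 lay at 0.69 and 0.70. A wrong material label is argued against by its position of 1.02 on the material axis, where OX3 is at 1. A wrong treatment label could account for the position of 0.26, and so could a weaker response in that sample, which the position does not separate from it: it lay beyond all 3 OX3 controls, in the direction seen in W, in 42% of the 200 genes, against 25% if it were exchangeable with them and 78.5% and 78% for replicates 2 and 3. OX3 control replicate 4 lay at the same position and beyond the other 2 controls in 66.5% of genes, against 33.3% if it were exchangeable with them, and exchanging these 2 libraries gave 742 genes for Mn over both materials against 740 as labelled.

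The 740 genes that differed with Mn over both materials had a median absolute log2 fold change of 1.42. A trend with gene length as the source of these calls is argued against, since 90.1% of them kept call and direction after it was removed. The Spearman correlation of fold change with gene length was -0.14 here, -0.29 for Mn in W and 0.33 for the interaction. The call on the interaction ended with the trend removed, so the argument covers the 740 genes only. Both outcomes written beforehand for the influence of 1 library were met. Fewer than 10% of the calls remained without any one of 9 libraries, so the calls lie near the threshold. The median fold change of the 740 genes stayed at 0.945 of its full value or more in all 12 fits. These genes were chosen in the fit of all 12 libraries, which favours that second outcome, so the influence of 1 library stays open. A Mn response common to both materials may contribute and stays open. Its test gave exactly the bound set beforehand as speaking against it (p = 0.05 over 200 relabellings); that bound was set aside after the result was seen, because a p that misses a threshold does not show that a common response was absent. The relabelling with the highest correlation, 0.70, lies above the real 0.50. Among genes of at least 10 CPM the real correlation was 0.66 (exact permutation p = 0.045) and the highest other 0.79. Without 1 library the exact permutation p ranged from 0.02 to 0.14. The test therefore does not decide for or against such a response.

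Splits of the libraries bear on each count. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For Mn in W, 1 split gave as many genes as the real 1, with 0 in the highest other. For Mn in OX3 all 10 gave as many as the real 0, with 0 in the highest other. For OX3 against W at 50 µM, 1 split gave as many as the real 5, with 0 in the highest other. For OX3 against W at control, 2 splits gave as many as the real 4, and the highest other, 159 genes, joined W control replicates 3 and 4 with OX3 control replicate 4. That points to a structure of the samples. Among the 4 splits that part all 3 same-numbered pairs, the highest other gave 0. For Mn over both materials 2 of 40 splits gave as many as the real 740, the other being the exchange that gave 742. The splits other than the real one were drawn at random from the possible ones, so such shares are estimates. Labels were exchanged within materials here, and within treatments for OX3 against W over both treatments. For OX3 against W over both treatments 2 of 40 gave as many as the real 47, and the highest other gave 367 and placed W control replicate 2 with OX3 control replicates 2 and 3. By these splits chance is not excluded for either count. If same-numbered control libraries are taken as pairs, which rests on the data and not on the labels, 1 of the 80 splits that part all 3 pairs gave as many as the real 47, with 1 gene in the highest other. This does not exclude chance, because these splits were chosen after the split with 367, which kept the 2 control libraries numbered 2 together and is left out of them, and with the replicate number as a block only 11 of the 47 passed. In DESeq2, other splits gave more genes than the real one for OX3 against W, with 1937 against 217 at control and 370 against 231 at 50 µM. For Mn the highest other was 97 against 1505 in W and 791 against 1071 in OX3. DESeq2 was not run on splits for the interaction or the averaged comparisons.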

How the results depend on the processing

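The averaged comparisons, the share on chromosome 16, the length-trend correction and the block within treatment were chosen after seeing the data. Counts of genes are given for Mn in W, Mn in OX3, OX3 against W at control and at 50 µM, the interaction, Mn over both materials and OX3 against W over both treatments, in that order, against 1, 0, 4, 5, 1, 740 and 47. DESeq2 gave 1505, 1071, 217, 231, 68, 4042 and 590, of which those at control and at 50 µM were exceeded by other splits of the libraries (1937 and 370). The replicate block gave 0, 0, 0, 0, 0, 0 and 11, and the block within treatment 0 for OX3 against W at control, at 50 µM and for the interaction, and 123 over both treatments. Each block leaves out W replicate 1 at 50 µM, and the block within treatment also OX3 replicate 4 at 50 µM. A count that changed with a block therefore need not reflect pairing. Apart from OX3 against W at control the numbers were not treated as possible pairs. For Mn in OX3 the correlations of deviations were -0.19, -0.02 and -0.08, and the other comparisons had 2 same-numbered pairs each. Limma-voom gave 0 at control and at 50 µM and 276 for Mn over both materials. With sample weights it gave 23 at 50 µM, 2 for Mn over both materials and 153 for OX3 against W over both treatments. On log2 FPKM with a pseudocount of 1 the counts were 2 for Mn in W, 9 at control, 20 at 50 µM and 0 for the interaction, and with 0.1 they were 10, 25 and 0 for the last 3 of these. Fitting only the 2 groups gave 0 at control and at 50 µM, and 1 for Mn in W, which was another gene. Without a filter on low counts, and with the length trend removed, the interaction gave 0. Leaving out 1 library gave ranges of 0 to 1, 0 to 8, 0 to 100, 0 to 3, 0 to 0, 0 to 1842 and 20 to 579. The share on chromosome 16 ranged from 6.74% to 53.6% in those fits, against 38.3% in the main fit. It was also lower in DESeq2, at 8.98% (Fisher's exact p = 1.52e-08). With the block within treatment it was 11.4% (Fisher's exact p = 0.00016), and in limma-voom with sample weights 18.3% (Fisher's exact p = 1.67e-12). The correlation of Mn responses ranged from 0.27 to 0.59 without 1 library and was 0.66 among genes of at least 10 CPM (exact permutation p = 0.045). That of OX3 against W at the 2 concentrations was 0.24 (exact permutation p = 0.085) and 0.41 among genes of at least 10 CPM (exact permutation p = 0.05), with a range of 0.11 (without OX3 control replicate 2) to 0.33 without 1 library. The relabellings took no account of replicate numbers. The cause of these changes was not tested. Of 804 values of 41 named-gene results under alternatives, 617 kept direction and side of the threshold, 154 fell short of it, 29 passed it and 4 reversed. Those 4 were Glyma.20G176500 for Mn in OX3, near 0 throughout at a log2 fold change of 0.10: -0.06 with either FPKM pseudocount, and -0.05 to 0.24 without 1 library, with 0.00 without OX3 replicate 3 at 50 µM. The 4 genes named for OX3 against W over both treatments passed in all 24 alternatives run. Depth limits genes near the floor, such as Glyma.16G161000 in OX3 and Glyma.16G214500 in W. The list tests planned with an estimated correlation or a block were not run, since the lists had no members.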

Other observations

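Adjacent genes tended to appear together among those that differed with Mn over both materials. Of the 739 such genes with a chromosome in their identifier, 29 pairs of neighbouring tested genes moved in the same direction and 3 in opposite directions. In 10000 shuffles the mean was 8.69 and the highest 22 (permutation p = 0.0001, one-sided, the smallest they can give, a test chosen after the calls were seen).

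The log2 fold changes of OX3 against W at 5 and at 50 µM were compared in a window of 200 tested genes, Glyma.16G144800 to Glyma.16G189100, set from the control libraries alone after the concentration on chromosome 16 had been seen. Their correlation across genes was 0.75 in that window. In 146 other windows of 200 genes the median was 0.13 and the highest 0.52. The first window was picked for its genes with a small p at control, and the others were not. That choice favours a high correlation, so the 0.75 is not a like comparison with the other windows. Of the 50 genes with the smallest p in the control libraries alone, 8 of the 9 in the window and 38 of the 41 elsewhere had the same direction at 50 µM, shares that were not shown to differ (two-sided Fisher's exact p = 0.56). In the model of all 12 libraries, 13 of the 50 genes with the smallest p at control lay on chromosome 16, and 12 of the 50 at 50 µM, against 1.83 expected.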
